A study of Mus musculus with 9 samples.

How the data were processed

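Gene expression was measured by RNA sequencing in BV2 cells, an immortalized line of mouse microglia, in 9 libraries: 3 of untreated cells (Control), 3 of cells given lipopolysaccharide (LPS) and 3 of cells given LPS with a treatment that the labels name Pilo (LPS+Pilo). The dose and duration of each treatment and the meaning of Pilo are not given in the sources used here. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were prepared with the TruSeq RNA kit. The labels call the libraries biological replicates without saying whether they came from separate cultures, so p-values here measure the spread between these libraries.

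The authors deposited 1 table of TPM (transcript abundance scaled to the same total in every library) with 55906 genes, 1 column per library and values rounded to 2 decimals. Each library sums to 1000000 within rounding, so TPM are shares: a rise in abundant genes lowers the values of the rest. Per the submitters' processing notes, fastp 0.19.5, STAR 2.7.1a and DESeq2 1.24.0 were used with the mouse genome build GRCm39. The program that computed TPM, the annotation, the strand setting, the treatment of reads with several matches and any filter are not given in the sources used here. Reads of antisense or overlapping genes, close paralogs and pseudogenes may therefore be assigned to the wrong gene. TPM hold no read counts, so the depth per library is unknown and the counting error of a single value cannot be given. The spread between the 3 libraries of a group is the precision used throughout.

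Gene symbols were taken by Ensembl identifier from GENCODE M21, which gave a symbol to 52081 genes; the RefSeq table added 0 more. That annotation belongs to the earlier build GRCm38, so no coordinates were used, and symbols follow the older naming. A further 492 entries of the table carry identifiers of assembled transcripts (MSTRG), of which 418 were tested. In all, 486 tested genes had no symbol.

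Genes with at least 1 TPM in at least 3 of the 9 libraries were kept, which left 11260. Values were transformed to log2(TPM + 1), which understates the fold change of genes with low values. All 9 libraries were fitted together in limma 3.58.1 (R 4.3.3) with 1 mean per group, contrasts between groups and moderated variances with a trend on expression, leaving 6 residual degrees of freedom. The comparisons were LPS with Control, LPS+Pilo with LPS and LPS+Pilo with Control. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the genes tested in each comparison, and genes with an adjusted p under 0.05 were called, with no fold threshold. Fold changes are given with the standard error of the fit (SE) and group levels as mean TPM with standard deviation (SD).

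Of 35 gene lists fixed in advance, the 29 with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists. The preset correlation makes the test liberal when members of a list vary together. Camera with an estimated correlation and limma's rotation test fry were therefore run as alternatives. Camera asks whether a list ranked apart from the other genes, whereas fry asks whether its members changed at all. Members were also adjusted within each list alone. None of the 16 symbols of a histone list matched the table, so that list was not analysed here. Another 5 lists held markers of other cell types and had too few measured members for a test.

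Genes were named by a fixed rule. It took the 10 largest increases and 10 largest decreases among called genes with a mean of at least 5 TPM in the higher group, no overlap between the replicates of the groups and an established symbol (5 of each for LPS+Pilo with Control). It also took up to 4 called members with the largest fold changes per list, and 18 genes that are always named. Exceptions chosen after their values were seen were the called entries ENSMUSG00000119895 and MSTRG.18989 and the genes Ccl3, Ccl4, Ccl5, Ccl7, Ccl12, Cxcl2, Lpl, Gpnmb, Lyz2, Cybb, Trem2, Nr4a1, Dusp5, Ifit1 and Ifit3 in LPS+Pilo with LPS. Further genes chosen in this way are not reported here. The groups, comparisons, lists, naming rule and the settings listed below as fixed in advance were chosen before the data were examined.

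Because LPS with Control and LPS+Pilo with LPS share the LPS libraries, overlaps and correlations between fold changes were set beside those of simulated data drawn from the residual spread with the same sharing. For correlations (1000 draws) these had no effects; for the overlap of LPS with LPS+Pilo over LPS (100 draws) they kept the LPS change and gave LPS+Pilo none of its own, and for the overlap of the comparisons with Control (100 draws) no effects. Ranges of simulated values hold the central 95% of draws. The values were also set beside those of independent lists of the same size. With 3 libraries the shared group cannot be split into parts of 2 each, so part of any excess may come from the shared libraries. This sharing was at first planned as an explanation to weigh, and its values are given with the overlap.

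Settings fixed in advance changed the pseudocount (0.1 or 5), the filter (none, or a mean of at least 5 TPM), the scaling (median of ratios, or quantile normalization), the variance model (no trend, or a robust trend), the libraries fitted (only the 2 groups compared, a block for the replicate number, or without each library in turn) and a fold threshold of 1 on the log2 scale. Added after the data were seen were removal of a trend with transcript length and GC content, the fit without Control replicate 1 and LPS replicate 3 together, and the overlap at unadjusted p. The pipeline was tested on simulated data, in 5 rounds with 200 changed genes each, built on the residual spread of these libraries with noise independent between genes. It recovered 18.2% of changes of 0.5 on the log2 scale, 70.7% of changes of 1 and 95.2% of changes of 2 in LPS+Pilo with LPS, with 3.92% false calls. With 12 changed genes per round (25 rounds, added after the data were seen) it recovered 1%, 34% and 72%. In LPS with Control it recovered 19.4%, 66.3% and 95.8%, with 6.66% false calls. The disease-associated microglia list, shifted by -0.30, was called by camera in 5 of 5 rounds, with 0 other lists called. As the noise was independent between genes, these rounds cannot show false calls of lists whose members vary together.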

Results

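The data were TPM of 11260 tested genes in 9 libraries of BV2 microglia, 3 each of Control, LPS and LPS+Pilo. Between 10726 and 11123 genes reached 1 TPM per library; sequencing depth was unknown. Ribosomal protein genes took 11.5% to 14.3% of the signal, the ferritin genes 4.50% to 5.94% and mitochondrially encoded genes 1.74% to 2.74%. Correlations were 0.971 to 0.986 within groups and 0.961 to 0.983 between groups. The first principal component (33.6% of variance) parted Control, at -34.6 to -23.6, from the treated libraries, at 4.61 to 19.9. The second (22%) crossed the groups: Control replicate 1 (34.0) and LPS replicates 1 and 2 (16.0 and 18.4) lay at one end, LPS replicate 3 (-21.5) and Control replicate 2 (-17.7) at the other.

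**Figure D1:**
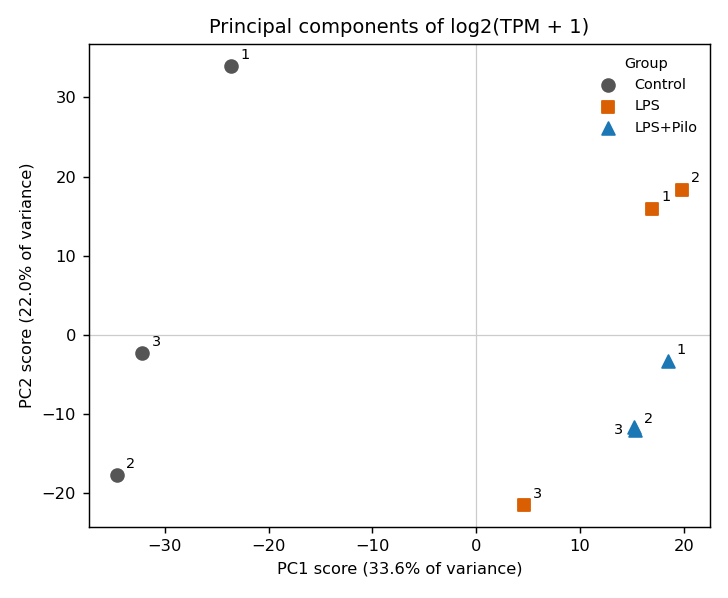
Scores of the 9 libraries (points, coloured by group, numbered by replicate) on the first and second principal components, with percent of variance on the axes. Control lay apart on the first component (33.6%), while the second (22%) spread Control and LPS libraries within their groups.

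The first comparison asked how LPS changed expression in BV2 cells. Lcn2, which encodes the siderophore-binding protein lipocalin, rose from 0.193 ± 0.0379 TPM in Control to 194 ± 54.1 TPM in LPS (mean ± SD, n = 3 per group), a log2 fold change of 7.32 ± 0.16 (SE; limma, Benjamini-Hochberg adjusted p = 2.47e-08). The chemokine genes Ccl7 and Ccl2, whose products draw monocytes, rose from 2.21 ± 0.326 to 149 ± 2.21 TPM (5.55 ± 0.14) and from 69.5 ± 5.52 to 894 ± 114 TPM (3.66 ± 0.12). Tnf, a central inflammatory cytokine gene, rose from 11.9 ± 1.06 to 190.3 ± 10.2 TPM (3.90 ± 0.10). Csf3, the gene of the granulocyte growth factor G-CSF, was listed at 0 in all 3 Control libraries and at 90.5, 49.8 and 38.3 TPM in LPS (adjusted p = 1.06e-06). Saa3, an acute-phase gene, rose by 4.80 ± 0.14, and Acod1, which encodes the enzyme that makes itaconate, by 3.98 ± 0.27. Pilra (3.55 ± 0.14), an inhibitory myeloid receptor gene, also rose. So did Nfkbiz (3.39 ± 0.26) and Zc3h12a (3.33 ± 0.11), which encode an NF-kB cofactor and an RNase that degrades cytokine mRNA. Each of these 10 genes was higher in 3 of 3 LPS libraries than in any Control library, as the naming rule required. Each kept its call in every alternative run.

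Asb10, which encodes an ankyrin-repeat protein with a SOCS box, fell by 2.81 ± 0.13, from 34.1 ± 2.31 to 4.01 ± 0.255 TPM (adjusted p = 2.52e-06). Serpinb1a, encoding an inhibitor of neutrophil proteases, fell by 2.25 ± 0.29, from 83.8 to 17.3 TPM. The orphan receptor gene Gpr157 fell by 1.93 ± 0.13, the CXCL12 receptor gene Cxcr4 by 1.91 ± 0.19 and the oxysterol receptor gene Gpr183 by 1.74 ± 0.16. The epoxide hydrolase gene Ephx1 fell by 1.69 ± 0.13, the leukocyte actin-binding gene Lsp1 by 1.66 ± 0.12 and the PI3-kinase inhibitor gene Pik3ip1 by 1.60 ± 0.14. Calls of 2 further transcripts are uncertain because reads of related or overlapping genes cannot be told apart: the pseudogene Nxpe1-ps (-1.66) and Hectd2os (-1.64 ± 0.33, adjusted p = 0.0154), named as antisense. Hectd2os no longer passed without Control replicate 3 (adjusted p = 0.0680) or LPS replicate 1 (0.0608), and its adjusted p ran from 0.00135 to 0.0680 over the alternatives.

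**Figure D2:**
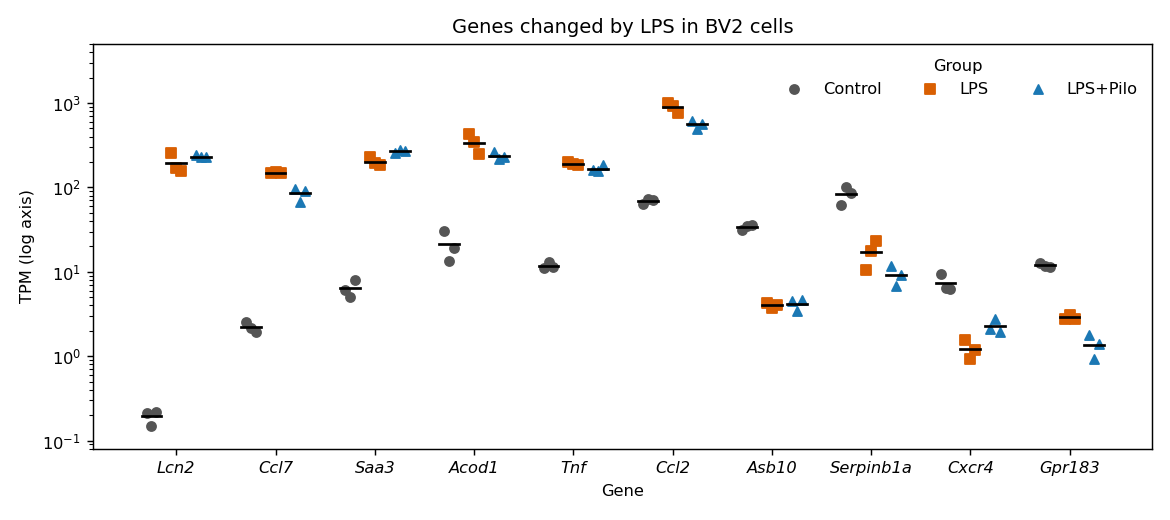
TPM (log axis) of Lcn2, Ccl7, Saa3, Acod1, Tnf, Ccl2, Asb10, Serpinb1a, Cxcr4 and Gpr183 in each library (points) with the group mean (bar), n = 3 per group. Tnf, for example, averaged 11.9 TPM in Control, 190.3 in LPS and 166 in LPS+Pilo, while Asb10 averaged 34.1, 4.01 and 4.20 TPM.

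In all, 874 of 11260 genes passed, 464 higher and 410 lower in LPS, with 239 changed by at least 1 on the log2 scale (168 higher, 71 lower). Replicates of the groups did not overlap for 873 of them and for 24.2% of all genes, where chance gives 10%. Without Control replicate 2 the count was 552, without Control replicate 3 414, without LPS replicate 1 507 and without LPS replicate 2 466. The share of higher genes moved too, with 671 higher and 327 lower without Control replicate 1 and 688 and 332 without LPS replicate 3. Fitting only the LPS and Control libraries gave 486 genes and quantile normalization 1516.

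Chemokine genes rose as a group: 9 of 10 measured members were higher, 1 was lower and 0 failed to pass, with the same counts adjusted over the list alone. Besides Ccl7 and Ccl2, the neutrophil chemokine gene Cxcl2 rose by 3.03 ± 0.32, from 0.143 to 9.29 ± 5.62 TPM, and Ccl12 by 2.87 ± 0.28. Cxcl10, a ligand of CXCR3, rose by 2.30 ± 0.24. The list had a median of 2.56 (camera adjusted p = 1.49e-13) and was the only one of the 29 to pass with an estimated correlation (adjusted p = 0.0279). Among proinflammatory cytokines 8 of 11 were higher, 0 lower and 3 did not pass (over the list alone 8 higher and 2 lower). Il6, a gene of systemic inflammation, rose by 2.44 ± 0.28, from 0.0167 to 4.85 ± 2.15 TPM, and Ebi3, which encodes a subunit shared by IL-27 and IL-35, by 2.11 ± 0.11. The median was 1.03 (camera adjusted p = 5.06e-05, adjusted p = 0.263 with an estimated correlation). Il1b, the interleukin-1 beta gene, stayed low, at 0.137 TPM in Control and 1.31 TPM in LPS (1.03 ± 0.25, adjusted p = 0.0366). It did not pass without Control replicate 2 (0.105) or 3 (0.138), LPS replicate 1 (0.113) or 2 (0.106) or LPS+Pilo replicate 3 (0.0546), with a range of 0.0118 to 0.138 over the alternatives.

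Inflammatory effectors and surface markers rose in 16 of 23 members, with 1 lower and 6 not passing (over the list alone 17 higher and 1 lower). Nos2, the inducible nitric oxide synthase gene, rose by 2.90 ± 0.33, from 0.0700 to 7.70 ± 4.58 TPM, and Ptgs2, which encodes COX-2, by 1.61 ± 0.27, from 0.743 to 4.63 TPM. The list median was 1.20 (camera adjusted p = 1.31e-17, adjusted p = 0.0775 with an estimated correlation). Of 24 NF-kB regulators 13 were higher, 0 lower and 11 did not pass (over the list alone 16 higher), among them Bcl3 (2.80) and Nfkbid (2.38), which encode nuclear inhibitor-kappa-B proteins. Their median was 0.72 (camera adjusted p = 1.25e-12, adjusted p = 0.406 with an estimated correlation). Immediate-early genes were higher in 8, lower in 1 and not passing in 15 of 24 (over the list alone 12 higher and 2 lower), led by Ier3 (2.46) and the AP-1 gene Fosl1 (2.07). Their median was 0.48 (camera adjusted p = 1.58e-04, adjusted p = 0.743 with an estimated correlation).

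Interferon-stimulated genes were higher in 7 of 36 members, lower in 0 and not passing in 29 (over the list alone 12 higher). Isg15, which encodes a ubiquitin-like modifier, rose by 1.13 (adjusted p = 0.0132; 0.0538 without LPS replicate 1; range 0.00683 to 0.0538 over the alternatives). The list median was 0.58 (camera adjusted p = 6.90e-05), with an adjusted p = 0.743 with an estimated correlation and 0.225 in fry. NRF2 antioxidant genes were higher in 4, lower in 0 and not passing in 15 of 19 (over the list alone 10 higher). Slc7a11, the cystine transporter gene, rose by 2.16 and the ferritin heavy chain gene Fth1 by 0.86. Fth1 fell short of the threshold under quantile normalization (0.23, adjusted p = 0.498; range 6.61e-04 to 0.498 over the alternatives). The list median was 0.34 (camera adjusted p = 0.00207, adjusted p = 0.686 with an estimated correlation).

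Lists on the lower side moved little. Of 49 cytosolic ribosomal protein genes 0 passed in either direction, over all genes or the list alone, with 8 lower at an unadjusted p under 0.05 (limma). Their median was -0.14 (camera adjusted p = 1.26e-04, adjusted p = 0.686 with an estimated correlation). The list did not pass without LPS replicate 1 (0.0535) or under quantile normalization (0.130; range 8.49e-12 to 0.686 over the alternatives). Of 32 nuclear-encoded oxidative phosphorylation genes 0 passed over all genes or the list alone, with 8 lower and 1 higher at an unadjusted p under 0.05 (limma). Their median was -0.11 (camera adjusted p = 0.00460, adjusted p = 0.344 with an estimated correlation). This list also missed the threshold without LPS replicate 1 (0.0535; range 2.52e-04 to 0.344 over the alternatives). Cholesterol biosynthesis genes were lower in 3, higher in 0 and not passing in 19 of 22 (over the list alone 4 lower). Dhcr7, which encodes the last enzyme of cholesterol synthesis, fell by 0.43 (adjusted p = 0.0143; 0.0645 without Control replicate 3; range 0.00183 to 0.0645 over the alternatives). The list median was -0.13 (camera adjusted p = 0.0386, adjusted p = 0.743 with an estimated correlation). Its adjusted p was 0.0567 without Control replicate 1, 0.0535 without LPS replicate 1 and 0.102 without LPS replicate 3 (range 0.00153 to 0.743 over the alternatives). Fry passed 7 of the 10 lists called by camera. These were chemokines (adjusted p = 9.29e-07), cytokines (2.62e-05), inflammatory effectors (2.62e-05) and NF-kB regulators (8.37e-04). The others were NRF2 (0.0346), immediate-early (0.0451) and oxidative phosphorylation genes (0.0451). Fry did not pass interferon-stimulated (0.225), ribosomal protein (0.217) or cholesterol genes (0.364).

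Microglial state markers went both ways. Of 28 disease-associated microglia markers 6 were higher, 5 lower and 17 did not pass (over the list alone 8 higher and 12 lower), with a median of -0.17, a mean of 0.03 and a camera adjusted p = 0.164, toward lower. Spp1, which encodes osteopontin, rose by 1.41, from 668 to 1784 TPM, and the inhibitory receptor gene Lilrb4a by 1.48. Of 19 homeostatic markers 2 were higher, 4 lower and 13 did not pass, with the same split over the list alone (adjusted p = 0.230). The integrin gene Itgam rose by 1.58 and the Fc receptor-like gene Fcrls fell by 0.90. Tmem119 (0.24, adjusted p = 0.327) and the fractalkine receptor gene Cx3cr1 (-0.15, adjusted p = 0.635) did not pass. Of 8 alternative activation markers 3 were higher, 2 lower and 3 did not pass (over the list alone 5 higher and 2 lower; camera adjusted p = 0.0812, 0.00725 in fry). Il1rn, the interleukin-1 receptor antagonist gene, rose by 2.96, from 12.6 to 106 TPM, and the scavenger receptor gene Msr1 by 2.58. Complement and phagocytic receptor genes were higher in 6, lower in 4 and not passing in 8 of 18 (over the list alone 7 higher and 5 lower), with C3 up by 1.57, Cfp (properdin) up by 1.43 and C1qc at -1.25. That list had a median of -0.09 and a mean of 0.14 (adjusted p = 0.877, toward lower).

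Other lists did not pass camera with all libraries. Of 27 TLR and inflammasome genes 3 were higher and 0 lower (adjusted p = 0.139), led by Casp4 (1.35), the sensor of intracellular LPS. Among 17 p53 target and apoptosis genes 4 were higher and 1 lower (adjusted p = 0.0520), led by Gadd45a (1.66), and among 21 unfolded protein response genes 3 were higher and 0 lower (adjusted p = 0.174), led by Trib3 (1.19). Of 28 lysosome and autophagy genes 0 were higher and 2 lower (median 0.01, mean -0.07; adjusted p = 0.164, toward lower), with the lysosomal regulator gene Tfeb at -1.29. Of 14 HIF1 targets 0 were higher and 3 lower (adjusted p = 0.195), with Ankrd37 at -1.59. MHC class I genes were higher in 2 of 16 (adjusted p = 0.0812), and 1 of 7 MHC class II genes was lower (adjusted p = 0.164), the maturation marker gene Cd83 (-1.09). Adjusted p was 0.192 for glycolysis (2 higher, 1 lower of 21), 0.225 for the TCA cycle (0 higher, 2 lower of 22; median 0.01, mean -0.02, toward lower) and 0.225 for mitochondrially encoded genes (0 of 13). It was 0.164 for DNA replication and mitosis (1 higher, 1 lower of 40), 0.164 for heat shock proteins (0 of 13), 0.263 for fatty acid synthesis and LXR targets (1 higher, 1 lower of 18) and 0.664 for TGF-beta targets (2 higher of 10). The remaining members of these lists did not pass. Over the list alone the split differed from that over all genes for the unfolded protein response (4 higher), lysosome (2 higher, 5 lower), HIF1 (1 and 4), MHC class II (1 and 1), glycolysis (3 and 1), TCA cycle (1 and 4) and fatty acid (1 and 2) lists. With an estimated correlation the 19 lists that did not pass had adjusted p from 0.686 to 0.953. At an unadjusted p under 0.05 (limma) 2 mitochondrially encoded genes were lower and 3 heat shock genes higher.

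**Figure D3:**
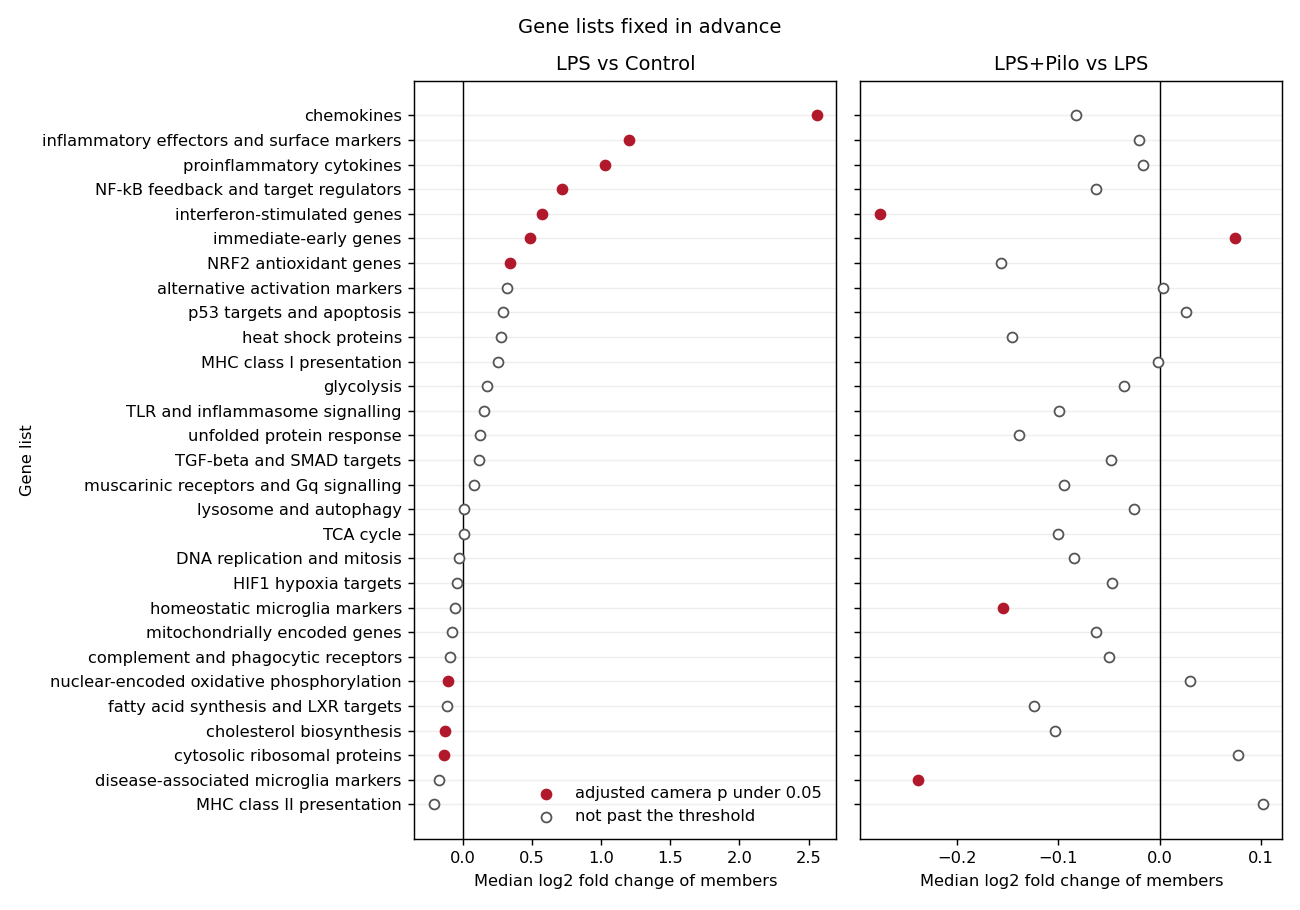
Median log2 fold change of each of 29 gene lists in LPS against Control and in LPS+Pilo against LPS, with filled red points for a camera adjusted p under 0.05. Chemokines had the median 2.56 with LPS and -0.08 for LPS+Pilo against LPS.

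The 5 muscarinic receptor genes were among the 18 genes that are always named. Chrm1, Chrm2 and Chrm5 were listed at 0 in all 9 libraries. Chrm3, the M3 receptor gene, was listed at 0 except for 0.01 TPM in LPS replicate 2 and 0.02 TPM in LPS+Pilo replicate 1. Chrm4 ranged from 0.08 to 0.36 TPM. None of the 5 reached the filter, so none was tested. Of 12 measured genes of muscarinic and Gq signalling 1 was higher, 2 lower and 9 did not pass with LPS, with the same split over the list alone (median 0.08, mean -0.04, adjusted p = 0.448, toward lower). Rgs2, a regulator of Gq signalling, fell by 1.15 (adjusted p = 0.0172) and missed the threshold without Control replicate 2 (0.0529), Control replicate 3 (0.0654) or LPS replicate 2 (0.0507), with a range of 0.00392 to 0.0654 over the alternatives. For LPS+Pilo against LPS 0 of the 12 passed (1 lower over the list alone and at an unadjusted p under 0.05 in limma; camera adjusted p = 0.981). Also below the filter were Il10 (0 to 0.04 TPM), Arg1 (0 to 0.3 TPM), Mrc1 (0 to 0.06 TPM) and P2ry12 (0 to 0.4 TPM). Of 54 markers of other cell types 48 averaged under 0.5 TPM and 6 were tested; Syn1, a synaptic vesicle gene, was the only one of these called with LPS (0.93, from 5.39 to 11.4 TPM, adjusted p = 0.00929).

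The comparison of LPS+Pilo with LPS asked what Pilo added to the response. Igf1, which encodes insulin-like growth factor, fell by 1.48 ± 0.16 (adjusted p = 0.0216), with 44.9 ± 3.20 TPM in Control, 29.0 ± 5.15 in LPS and 9.79 ± 1.92 in LPS+Pilo (SD, n = 3 per group). Hspb7, a small heat shock protein gene, fell by 0.84 ± 0.10 (adjusted p = 0.0342), with 203 ± 18.7, 85.4 ± 8.92 and 47.0 ± 2.54 TPM. Plau, the gene of urokinase plasminogen activator, fell by 0.66 ± 0.09 (adjusted p = 0.0481), with 112 ± 7.52, 76.2 ± 2.87 and 47.9 ± 2.87 TPM. ENSMUSG00000119895, a gene without a symbol here, was listed at 0 in all Control and LPS+Pilo libraries and at 7.61, 9.56 and 27.3 TPM in LPS (adjusted p = 0.0196). The assembled transcript MSTRG.18989 rose by 1.54 ± 0.17 (adjusted p = 0.0216), with 1.21, 0.407 and 3.08 TPM. These were all 5 of the genes that passed, 1 higher and 4 lower, each without overlap in 3 of 3 libraries. The calls of ENSMUSG00000119895 and MSTRG.18989 are uncertain, since reads of related or overlapping genes cannot be told apart.

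Each of the 5 calls was lost without at least 3 of the single libraries. Igf1 missed the threshold without LPS replicate 2 (0.112) or 3 (0.0959) or LPS+Pilo replicate 1 (0.0837), 2 (0.126) or 3 (0.169), with a range of 0.0137 to 0.169 over the alternatives. Hspb7 missed it without Control replicate 3 (0.0522), LPS replicate 1 (0.0860), 2 (0.125) or 3 (0.0959) or LPS+Pilo replicate 1 (0.139), 2 (0.186) or 3 (0.169), with a range of 0.0231 to 0.206. Plau missed it without Control replicate 2 (0.106) or 3 (0.0668), LPS replicate 1 (0.0992), 2 (0.272) or 3 (0.197) or LPS+Pilo replicate 1 (0.136), 2 (0.264) or 3 (0.328), with a range of 0.0407 to 0.328. ENSMUSG00000119895 missed it without LPS+Pilo replicate 1 (0.0971), 2 (0.126) or 3 (0.169), with a range of 0.00237 to 0.169; without an LPS library it fell under the filter and was not tested. MSTRG.18989 missed it without LPS replicate 1 (0.0860), 2 (0.112) or 3 (0.0648) or LPS+Pilo replicate 1 (0.136), 2 (0.126) or 3 (0.169), with a range of 0.0137 to 0.169. The count was 1 without LPS replicate 1 (1 shared with the 5) and 1 without LPS replicate 2 (0 shared). It was 0 in limma without LPS replicate 3 (1243 genes at an unadjusted p under 0.05) or LPS+Pilo replicate 1 (830), 2 (543) or 3 (476). With all libraries 761 genes had an unadjusted p under 0.05, where 563 are expected without any effect, and 12.2% of all genes had no overlap, where chance gives 10%.

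The inflammatory genes named here, raised by LPS, did not pass between LPS+Pilo and LPS with all libraries. Tnf had a log2 fold change of -0.20 (adjusted p = 0.771; 190.3 TPM in LPS, 166 in LPS+Pilo), Il6 0.04 (0.989), Il1b 0.20 (0.917), Nos2 0.30 (0.906), Ptgs2 -0.02 (0.996) and Cxcl10 -0.58 (0.705). The monocyte chemokine genes had lower values, Ccl2 -0.68 (0.212; 894 and 558 TPM), Ccl7 -0.82 (0.207; 149 and 85.0 TPM) and Ccl12 -0.98 (0.502). Ccl2 passed without Control replicate 1 and LPS replicate 3 together (-0.78, limma adjusted p = 0.0495), a setting added after the data were seen. In that setting the median of all genes was -0.13. The adjusted p of Ccl2 ran from 0.0495 to 0.669 over the alternatives. Ccl3 (-0.03, 0.979), Ccl4 (-0.03, 0.978) and Ccl5 (0.05, 0.981), which encode other CC chemokines, were near 0, and Cxcl2 was at 1.09 (0.502). Over the list of 10 chemokines alone 1 was higher and 3 lower, while 0 passed over all genes. At an unadjusted p under 0.05 in limma 1 was higher and 4 lower. The camera adjusted p of that list was 0.118, with a range of 0.00957 to 0.997 over the alternatives. Cytokines (0 of 11; 1 lower at unadjusted p; adjusted p = 0.981), NF-kB regulators (0 of 24; 2 lower over the list alone; adjusted p = 0.991) and inflammatory effectors (1 lower of 23, Plau; 3 lower over the list alone; adjusted p = 0.869) did not pass either.

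**Figure D4:**
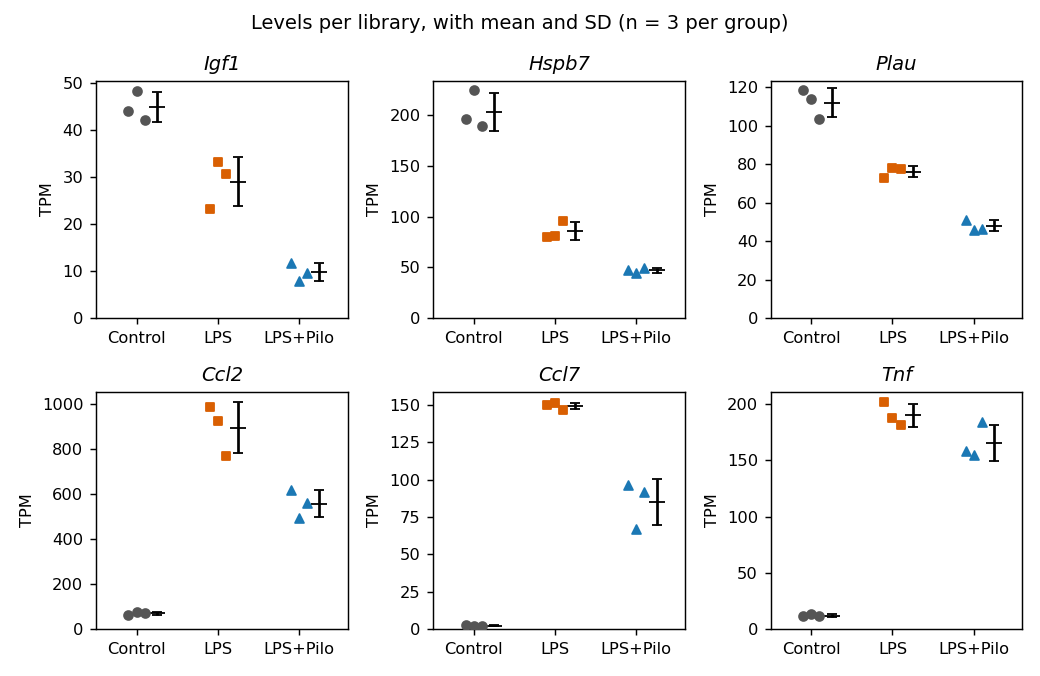
TPM of Igf1, Hspb7, Plau, Ccl2, Ccl7 and Tnf in each library (points) with mean and SD, n = 3 per group. Igf1 averaged 44.9, 29.0 and 9.79 TPM in Control, LPS and LPS+Pilo, and Ccl2, which did not pass between LPS+Pilo and LPS, 69.5, 894 and 558 TPM.

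Camera passed 4 of 29 lists, 1 toward higher and 3 toward lower in LPS+Pilo. Each had an adjusted p = 0.997 with an estimated correlation, and fry passed 0 lists (2 at an unadjusted p under 0.05; 1 for the estimated correlation). Disease-associated microglia markers were negative in all but 3 of 28 (median -0.24, mean -0.30, camera adjusted p = 2.37e-08; 0.194 in fry). Over all genes 0 of them passed, over the list alone 10 were lower, and 14 were lower at an unadjusted p under 0.05 (limma). Among the members, Lpl, the lipoprotein lipase gene, was at 182, 121 and 60.0 TPM in Control, LPS and LPS+Pilo (-0.98, adjusted p = 0.255). Further values were Gpnmb -0.56 (0.255), Lyz2 -0.76 (0.271), Cybb -1.07 (0.321) and the lipid receptor gene Trem2 -0.48 (0.392). Lpl (-1.11) and Gpnmb (-0.64) passed without Control replicate 1 and LPS replicate 3 together (limma adjusted p = 0.0495 for each). Over the alternatives their adjusted p ran from 0.0495 to 0.787. In that setting, added after the data were seen, the median of all genes was -0.13. The list passed without each library in turn, with medians from -0.30 to -0.21.

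Homeostatic markers passed camera toward lower (median -0.16, adjusted p = 0.0215). Of 19 members 0 passed, 3 were lower over the list alone and 4 at an unadjusted p under 0.05 (limma). Cx3cr1 was at 3.42, 2.91 and 1.13 TPM (-0.87, adjusted p = 0.265) and Tmem119 at 0.02 (0.987). The list did not pass without LPS replicate 3 (0.0945) or LPS+Pilo replicate 1 (0.128), with a range of 0.00779 to 0.997 over the alternatives. Interferon-stimulated genes also passed toward lower (median -0.28, adjusted p = 0.00946), with 0 of 36 members passing over all genes or the list alone and 2 lower at an unadjusted p under 0.05 (limma). Ifit1 was at -0.56 (0.598) and Ifit3 at -0.66 (0.530). The list did not pass without LPS replicate 1 (0.264) or LPS+Pilo replicate 2 (0.0991), with a range of 4.03e-04 to 0.997 over the alternatives. Immediate-early genes passed toward higher (median 0.07, adjusted p = 0.0215), with 0 of 24 passing, 1 higher over the list alone and 4 at an unadjusted p under 0.05 (limma). The activity-induced genes Nr4a1 (9.83, 5.74 and 11.7 TPM; 0.93, adjusted p = 0.212) and Dusp5 (0.69, 0.502) had higher values. This list missed the threshold without LPS replicate 2 (0.102), LPS replicate 3 (0.215), LPS+Pilo replicate 2 (0.0942) or LPS+Pilo replicate 3 (0.0558), with a range of 2.50e-04 to 0.997 over the alternatives. Without LPS+Pilo replicate 2 camera passed 2 lists.

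The other 25 lists did not pass with all libraries. Adjusted p was 0.0520 for ribosomal proteins (0 of 49; median 0.08), 0.139 for NRF2 genes (0 of 19; median -0.16), 0.141 for oxidative phosphorylation (0 of 32; median 0.03), 0.144 for heat shock proteins (0 of 13; median -0.15), 0.209 for the unfolded protein response (0 of 21; median -0.14) and 0.232 for cholesterol biosynthesis (0 of 22; median -0.10). At an unadjusted p under 0.05 (limma) 6 unfolded protein response genes were lower and 1 higher, 4 oxidative phosphorylation genes were higher and 1 lower, and the other 4 lists had at most 2 genes in a direction. Over the list alone 1 NRF2 gene was higher and 1 lower, and 0 passed in the other 5. Alternative activation markers had 1 of 8 lower, Igf1, with a median of 0.00, a mean of -0.29 and an adjusted p = 0.504. The lists not named in this comparison so far had adjusted p from 0.309 to 0.991. Median, mean and test differed in sign for 5 of 29 lists. These were alternative activation markers, p53 targets (median 0.03, mean -0.03, toward lower) and cytokines, MHC class I and HIF1 targets, where both averages were below 0 and the test leaned toward higher.

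A reversal of the LPS response by Pilo was asked among the 874 genes changed with LPS. Of the 5 genes that passed for LPS+Pilo against LPS, 2 moved opposite to the LPS change (ENSMUSG00000119895 and MSTRG.18989) and 3 in the same direction as it (Igf1, Hspb7 and Plau, lower at both steps). The 2 opposite entries are the uncertain calls without a symbol. Independent lists of these sizes give 0.201 opposite and 0.187 in the same direction. Simulations that kept the LPS change and gave LPS+Pilo none of its own had a median of 0 for each, and the interpolated upper end of the central 95% of draws was 5.675 opposite and 0 in the same direction. At unadjusted p the counts were 82 opposite and 74 in the same direction, against 29.7 and 29.3 for independent lists and simulated medians of 53 and 11 (upper ends of the central 95% of draws 1362 and 139). Of the 464 genes higher with LPS 263 had a negative log2 fold change for LPS+Pilo against LPS (median -0.050), and of the 410 lower genes 197 did (median 0.003). The median over all 11260 tested genes was -0.046, so the genes higher with LPS lay near the shift of all genes. The genes lower with LPS (median 0.003) lay slightly above it, opposite to their LPS change. The shared LPS libraries alone can also give a movement in that direction. The fold changes correlated at -0.18, against a simulated median without effects of -0.52 (central 95% of draws -0.89 to 0.11), with a covariance of -0.0211 against a simulated -0.0328 (-0.0762 to 0.00391). Those draws held no LPS change, which the real fold changes did, so the correlations are not like for like. Both real values lay within the simulated ranges. The opposite count was 1 without Control replicate 2 or 3 and 0 without any 1 of the LPS or LPS+Pilo libraries.

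LPS+Pilo against Control asked how far the doubly treated cells stayed from untreated cells. Lcn2 was higher by 7.61 ± 0.16 (0.193 ± 0.0379 and 232 ± 8.40 TPM, n = 3 per group; adjusted p = 1.70e-08), Saa3 by 5.22 ± 0.14, Ccl7 by 4.73 ± 0.14 and Cxcl2 by 4.11 ± 0.32. Csf3, listed at 0 in Control, was at 73.9, 80.7 and 77.3 TPM (adjusted p = 6.22e-07). The inflammatory genes Tnf (3.69), Nos2 (3.20), Ccl2 (2.98), Il6 (2.49), Cxcl10 (1.72) and Ptgs2 (1.59) were also called. Il1b (0.137 and 1.77 TPM, adjusted p = 0.0133) missed the threshold without Control replicate 3 (0.0564; range 0.00742 to 0.0564 over the alternatives). Serpinb1a fell by 3.05, Asb10 by 2.76, Gpr183 by 2.47 and the pseudogene Nxpe1-ps, an uncertain call, by 2.36. The fractalkine receptor gene Cx3cr1 fell by 1.03 ± 0.18 (adjusted p = 0.00582), which had not passed between LPS and Control; Tmem119 was at 0.26 (adjusted p = 0.275). Whether Cx3cr1 differed between these comparisons was tested by LPS+Pilo against LPS, where it did not pass.

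The ribosomal pseudogene Rpl39-ps was also called and is uncertain, since its reads may come from the parent gene. It was listed at 0 in all LPS+Pilo libraries and LPS replicate 3, and at 20.6, 13.8 and 55.6 TPM in Control (adjusted p = 0.0391). It missed the threshold without Control replicate 1 (0.0609), 2 (0.0568) or 3 (0.134), LPS replicate 2 (0.0531) or LPS+Pilo replicate 1 (0.106), 2 (0.115) or 3 (0.108), with a range of 6.82e-04 to 0.134 over the alternatives. In all, 1143 genes passed, 546 higher and 597 lower, with 310 changed by at least 1 on the log2 scale (196 higher, 114 lower). Replicates did not overlap for 1142 of them and for 30.5% of all genes, where chance gives 10%. The count was 642 without Control replicate 3, 735 without LPS+Pilo replicate 1, 663 without LPS+Pilo replicate 2 and 692 without LPS+Pilo replicate 3; quantile normalization gave 1726. With LPS against Control 668 called genes were shared in the same direction and 1 in the opposite, against 44.2 and 44.5 for independent lists and simulated medians of 0 and 0. The fold changes correlated at 0.82, against a simulated median of 0.52 (-0.13 to 0.89), with a covariance of 0.165 against a simulated 0.0322. The Control libraries are shared. Since these simulations held no effects, they cannot show how far that sharing adds to the overlap of genes that do change.

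Camera passed 10 of 29 lists, 5 in each direction, and with an estimated correlation 1 passed. Chemokines were higher in 9 and lower in 1 of 10, as over the list alone (adjusted p = 1.04e-12, adjusted p = 0.0332 with an estimated correlation). Inflammatory effectors were higher in 16, lower in 1 and not passing in 6 of 23 (over the list alone 18 and 1; adjusted p = 1.39e-15, adjusted p = 0.103 with an estimated correlation). NF-kB regulators were higher in 12 and not passing in 12 of 24 (over the list alone 14 higher; adjusted p = 3.96e-11, adjusted p = 0.616 with an estimated correlation). Immediate-early genes were higher in 12, lower in 1 and not passing in 11 of 24 (over the list alone 13 and 1; adjusted p = 1.94e-06, adjusted p = 0.756 with an estimated correlation). Cytokines were higher in 8, lower in 2 and not passing in 1 of 11 (over the list alone 8 and 3; adjusted p = 3.39e-05, adjusted p = 0.255 with an estimated correlation).

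On the lower side, disease-associated microglia markers were lower in 11, higher in 3 and not passing in 14 of 28 (over the list alone 14 and 3; median -0.27, adjusted p = 0.00104, adjusted p = 0.756 with an estimated correlation). Cholesterol genes were lower in 5 and not passing in 17 of 22, with 5 over the list alone (median -0.25, adjusted p = 0.00343, adjusted p = 0.774 with an estimated correlation). Homeostatic markers were lower in 6, higher in 2 and not passing in 11 of 19 (over the list alone 7 and 4; median -0.45, adjusted p = 0.0332, adjusted p = 0.787 with an estimated correlation). That call was lost without Control replicate 1 (0.0729), 2 (0.0866) or 3 (0.102), with a range of 0.00381 to 0.787 over the alternatives. DNA replication and mitosis genes were lower in 2, higher in 1 and not passing in 37 of 40 (over the list alone 4 and 1; median -0.15, adjusted p = 0.0332, adjusted p = 0.841 with an estimated correlation). The call was lost without Control replicate 1 (0.0729) or LPS+Pilo replicate 2 (0.0850), with a range of 0.00356 to 0.841 over the alternatives. Ribosomal protein genes were lower in 3 and not passing in 46 of 49 (over the list alone 1 lower; median -0.07, adjusted p = 0.0406, adjusted p = 0.841 with an estimated correlation). They missed the threshold without Control replicate 2 (0.464) or 3 (0.102) or LPS+Pilo replicate 1 (0.0557) or 3 (0.0550), with a range of 1.80e-05 to 0.841 over the alternatives. Interferon-stimulated genes, with 5 higher, 0 lower and 31 not passing of 36 (over the list alone 7 higher and 2 lower), had an adjusted p = 0.0580. NRF2 genes, with 4 higher and 15 not passing of 19 (over the list alone 5 higher), had an adjusted p = 0.0645. The remaining 17 lists had adjusted p from 0.0938 to 0.981. Median and mean differed in sign for 3 lists that did not pass: complement genes (-0.03 and 0.07), the unfolded protein response (-0.19 and 0.17) and TGF-beta targets (-0.03 and 0.08).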

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

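The alternatives added after the data were seen were removal of the trend with transcript length and GC content, the fit without Control replicate 1 and LPS replicate 3 together, and the overlap at unadjusted p. Of the called named genes, 57 of 94 kept their call in every alternative run for LPS with Control, 0 of 5 for LPS+Pilo with LPS and 16 of 18 for LPS+Pilo with Control. No named gene or list called with all libraries changed sign, except the median of the cholesterol list in LPS with Control. It went from -0.13 to 0.06 without Control replicate 1 and LPS replicate 3 together, where its call ended and the test still leaned toward lower. Some lists not called with all libraries passed under an alternative. These were 8 in LPS with Control, 5 in LPS+Pilo with LPS and 6 in LPS+Pilo with Control. In LPS with Control the lowest camera adjusted p was 0.00623 for p53 targets, 0.0129 for MHC class I and 0.0160 for the unfolded protein response. It was 0.0197 for glycolysis, 0.0329 for DNA replication and 0.0380 for heat shock proteins. Alternative activation markers passed in fry. The TCA cycle list of LPS with Control (median 0.01) passed camera toward lower under an alternative (lowest adjusted p = 0.0424). Its medians ran from -0.09 to 0.19 over the alternatives. Depth is unknown, so its effect on genes with low TPM was not tested. Where no reason is given below, the cause was not tested.

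For LPS with Control, 874 genes were called. The fold threshold of 1 gave 239 by construction. Quantile normalization gave 1516 (40.5% higher, against 53.1%) and removal of the length and GC trend 1587. The fit of only the 2 groups compared gave 486. That fit had 4 residual degrees of freedom against 6 and left the LPS+Pilo libraries out of the variance estimate. These 2 differences were not told apart, and for LPS+Pilo with Control the same kind of fit gave 1061 genes against 1143. Leaving out Control replicate 1 and LPS replicate 3 together gave 3586 (2930 higher, 656 lower). These libraries lie at opposite ends of the second component, and the median of all genes moved to 0.20. Leaving out each library in turn gave 414 to 1020, and moved the median of all genes to 0.13 without Control replicate 1 and 0.14 without LPS replicate 3. Of 29 lists, 10 were called. The total was 1 with the estimated correlation and 8 with fry (7 shared with the 10). It was 16 with the length and GC trend removed and 7 to 11 without each library.

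For LPS+Pilo with LPS, 5 genes were called. The count was 3 with the fold threshold, 2 with a pseudocount of 5, 1 with no filter (0 shared with the 5; more genes tested), 1 with a mean of at least 5 TPM, 2 with median-of-ratios scaling, 1 with quantile normalization, 3 with no variance trend, 3 with only the 2 groups compared, 2 with the length and GC trend removed and 18 without Control replicate 1 and LPS replicate 3 together. Leaving out each library gave 0 to 6, and without LPS replicate 3 the median of all genes was -0.13. With all libraries 4 lists were called. The total was 1 with a mean of at least 5 TPM, 0 with the estimated correlation (1 at unadjusted p), 0 with fry (2 at unadjusted p) and 2 to 5 without each library, not always the same lists. The 2 genes moved opposite to LPS became 82 at unadjusted p, 0 with a pseudocount of 5 (limma), 1 with no filter, 0 with a mean of at least 5 TPM, 1 with quantile normalization, 1 with only the 2 groups compared, 9 without the pair of libraries and 0 to 2 without each library.

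For LPS+Pilo with Control, 1143 genes were called: 310 with the fold threshold, 1726 with quantile normalization (42.6% higher, against 47.8%), 2120 with the length and GC trend removed, 1967 without the pair of libraries and 642 to 1286 without each library. With all libraries 10 lists were called; the total was 1 with the estimated correlation, 6 with fry and 8 to 11 without each library, not always the same lists.

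Samples of different groups share only a replicate number. The choice not to use the numbers as pairs was fixed in advance, since the labels name no shared day or batch. Deviations from the group mean correlated at -0.23 to 0.165 for libraries with the same number and -0.37 to 0.30 for others. Of the 9 libraries, 4 correlated best with a library of their own number among the other groups. A block for the number gave 808, 1 and 1064 genes in the 3 comparisons, 10, 4 and 12 lists, and 1 gene opposite to LPS.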

Other observations

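Among the CC chemokines, the values of Ccl2, Ccl7 and Ccl12 relative to Ccl3, Ccl4 and Ccl5 were lower in LPS+Pilo than in LPS. The mean log2 level of the first 3 genes minus that of the others was -2.41 ± 0.16 in LPS and -3.24 ± 0.16 in LPS+Pilo (SD, n = 3 per group), a difference of -0.82. All 3 LPS+Pilo libraries (-3.08, -3.40 and -3.23) lay below all 3 LPS libraries (-2.57, -2.42 and -2.25). The exact permutation p was 0.1, the smallest that 3 against 3 libraries can give, and the genes were chosen after their values were seen.

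Tests of the replicate number, of power at changes of 0.5 and of power with 12 changed genes, and the exchange of labels between Control replicate 1 and LPS replicate 3, were chosen after the result was seen. The second principal component (22% of variance) ran within groups. The replicate number explained 0.483 of its variance within groups, and Control replicate 2 (-17.7) and LPS replicate 2 (18.4) lay at opposite ends, which argues against a batch shared by libraries of the same number as the whole cause. Gene loadings followed transcript length (Spearman 0.436) and GC content (-0.322), which together explained 17.2% of the variance of the loadings, so a difference in fragmentation or length bias between libraries may account for part of it. The rest of the component stays open, and no biological explanation was tested. Of 10 splits of the Control and LPS libraries, 2 called at least the 874 genes of the real one. The highest other split called 2650, with Control replicate 1 beside LPS replicates 1 and 2, and points to this structure of the samples.

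With the trend removed, the labels as given called 1587 genes and the exchange of Control replicate 1 and LPS replicate 3 called 104. In LPS markers both libraries stayed with their own groups: Tnf was at 11.1 TPM in Control replicate 1 and 182 TPM in LPS replicate 3, and Lcn2 at 0.21 and 154 TPM.

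LPS+Pilo against LPS called 5 genes, and leaving out any LPS library gave at most 1 gene. This fall cannot exclude one LPS library apart from the others, since leaving out any LPS+Pilo library gave 0 genes as well. Without LPS replicate 3 genes at an unadjusted p under 0.05 (limma) rose from 761 to 1243. Without it and Control replicate 1 together 18 genes were called, so one LPS library apart from the others stays open. Of simulated changes of 1 on the log2 scale 70.7% were recovered with 200 changed genes, but 34% with 12 changed genes, since the adjusted threshold depends on that number. For changes of 0.5 the recovery was 18.2% and 1%, so changes of 0.5, and some of 1, could be present and go uncalled. Whether Pilo left most of the response as it was or changed many genes slightly stays open.

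The disease-associated microglia list had a median of -0.24 for LPS+Pilo against LPS, with 0 of 28 members past the threshold over all genes and 14 lower at an unadjusted p under 0.05 (limma). Its camera call was lost with an estimated correlation (adjusted p = 0.997). Fry, which asks whether the members changed at all, did not pass it either (adjusted p = 0.194). Scaling between libraries is argued against, since the median stayed at -0.19 after median-of-ratios scaling, and so is a trend with expression, GC content or length (-0.21 after its removal) and a single library (at most -0.21 without any 1 of the 6). None of 10000 random lists matched on expression reached that median (0%), the lowest being -0.15. Those lists held unrelated genes, while members of this list varied together (estimated correlation 0.209). Their medians may therefore spread less, and the 0% does not measure chance for this list. Homeostatic (-0.16) and interferon-stimulated (-0.28) lists also had negative medians, so the shift was not particular to this list, and its source stays open.

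Splits of 3 against 3 libraries are too few for a share under 0.05, so only the counts are given. For lists in LPS with Control 2 of 10 splits gave at least the real 10 (highest other 10). For genes in LPS+Pilo with LPS 1 of 10 gave at least the real 5 (highest other 2), and for its lists 4 of 10 gave at least the real 4 (highest other 8). For LPS+Pilo with Control 1 of 10 gave at least the real 1143 genes (highest other 3) and 1 of 10 at least the real 10 lists (highest other 7). For genes moved opposite to LPS, 3 of 20 labelings of the LPS and LPS+Pilo libraries gave at least the real 2 (highest other 4).

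In 104 genes a single library had at least 5 TPM while the other 8 stayed under 0.1 TPM, from 3 such genes in LPS+Pilo replicate 3 to 23 in Control replicate 2.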
